A study of Homo sapiens with 4 samples.

How the data were processed

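Mature microRNAs (miRNAs) were measured in 4 samples of total RNA from HaCaT cells, an immortalized human keratinocyte line, on the nanoString nCounter human miRNA panel. In this assay each miRNA is joined to a sequence tag, hybridised to a coloured barcode and counted by imaging, without amplification. Per the labels, all 4 samples received siRNAs against NF2 and LATS2, which encode components of the Hippo pathway, and were kept at high density before TRIzol extraction. The siRNAs were combined with a plasmid for EGFP in 2 samples and with a plasmid for p72 in the other 2. p72, encoded by DDX17, is an RNA helicase associated with the Microprocessor, the complex that cuts primary miRNA transcripts. The group of each sample was taken from its transfection label and the replicate number from its title. The titles of the control samples also carry the word p72 in brackets, which was read as a tag of the series because the transfection labels of these samples name the siRNAs without p72. Nothing in the labels says that replicates came from separate cultures, so every p-value measures the spread between these samples, which may be technical. The titles number the p72 samples 1 and 2, but the transfection labels of both end in 1, so they may come from a single transfection.

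The deposited table gives one linear signal per probe and sample, and its unit was worked out from the values. It holds 822 probes: 800 for human miRNAs (10 of them shared by several miRNAs), 5 for mRNA references, 6 positive controls, 6 negative controls and 5 for plant or worm miRNAs. In each sample, 100% of the deposited signals of human miRNA and mRNA probes were a whole count times 1 factor, within 0.01 of the deposited value. The factors were 0.844 and 0.903 in the EGFP control samples and 1.10 and 1.71 in the p72 samples. Positive, negative, plant and worm probes stand in the same columns as whole counts without that factor. The factors brought the geometric mean of the 800 miRNA probes to 31.8, 31.7, 31.6 and 31.6. The software, the rule behind the factors and any step on background are not given in the sources used here. The lowest miRNA count was 1 in each sample, listed for 3 to 10 probes.

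The main test was fixed before the data were examined, as was the rule for detection. A miRNA counted as detected when its mean over the 4 samples exceeded the mean plus 2 SD of the negative controls, put on the scale of the miRNA probes with each sample's factor and averaged over samples (52.6). This left 168 miRNAs. The log2(signal + 1) of these was fitted with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a trend, no further scaling), and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. The estimated prior degrees of freedom were infinite. The fit therefore replaced each miRNA's own residual spread by the value at its level of a trend over all detected miRNAs. This residual SD ran from 0.223 (miR-21-5p) to 0.245 (miR-575) on the log2 scale. Fold changes are on the log2(signal + 1) scale and understate the change of miRNAs near background, since no background was subtracted. The overall level was summarised as the median log2 difference over detected miRNAs, with an exact two-sided permutation test of the sample medians. A total of 21 lists of miRNA families, clusters and cell type markers was written beforehand. The 12 lists with at least 3 detected members were tested with camera at a preset correlation of 0.01, two-sided, with Benjamini-Hochberg adjustment over the lists.

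The rule for named miRNAs took up to 12 per direction by size of change among those past the threshold, filled to 12 by lowest p among those whose p72 values both lay beyond both control values. It added the 5 of highest mean, members of highest mean of each list, and 15 miRNAs fixed beforehand. Members of lists that the text does not name are covered by the counts. miR-196b-5p, miR-4454 and miRNAs named outside the comparison were chosen after their values were seen. The replicate numbers were not treated as pairs, because no label ties same-numbered samples together.

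The analysis was tested on simulated data: counts for the 800 probes were drawn 20 times from the real means and sample factors with a negative binomial dispersion of 0.01, and 200 probes were changed in each draw. Among detected probes, the fit recovered 66.0% of those changed 1.5-fold, 96.9% of those changed 2-fold and 100% of those changed 4-fold. Of its calls, 2.57% were false. The simulation took the sample factors as exact, changed probes equally up and down, and drew noise independently for each probe. Its dispersion was assumed. It therefore holds no error of scaling, and its share of false calls is not that of the real data.

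The total over miRNA probes was 84011 and 92064 counts in the control samples and 124970 and 81254 in the p72 samples. Replicates differed by more than counting noise in both groups, by a chi-square test over the detected miRNAs (chi-square 1257 for the control pair and 512.9 for the p72 pair, 167 degrees of freedom), so neither pair was merged as one library listed again. Repeat lanes of 1 RNA could differ as much, so this does not show that the samples are independent. The panel holds no probe for DDX17, NF2 or LATS2, so the p72 plasmid and the knockdowns were not checked here.

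Alternatives fixed beforehand were other scalings (the median of the detected miRNAs, the miRNA total, the mRNA references or the positive controls set equal), quantile normalization, no filter and a filter 4 times higher, pseudocounts of 10 and 32, limma without trend or with robust = TRUE, the replicate number as a block, each sample left out in turn, camera with an estimated correlation, and fry. Chosen after seeing the data were edgeR 4.0.16 (quasi-likelihood test, with the deposited factors or with TMM) and DESeq2 1.42.0 on the recovered counts, counts without scaling, scaling by RPL19 and RPLP0, subtraction of the mean negative control with a floor of 1, negative controls left unscaled in the filter, and crossed replicate numbers as a block. On the recovered counts, edgeR with the deposited factors called 117 miRNAs. miRNA genes that neighbour each other were taken from RefSeq (assembly GRCh38.p14), used for names and neighbourhood only, for the 138 of 168 detected probes that matched a single gene. Figures were drawn with matplotlib 3.10.9.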

Results

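The levels of 800 human miRNAs were compared between HaCaT keratinocytes given a p72 plasmid (n = 2) and cells given an EGFP plasmid (n = 2), where n counts samples and the labels leave open whether the p72 pair was 1 transfection, all of them also transfected with siRNAs against NF2 and LATS2. The comparison asks whether added p72, a helicase of the miRNA processing machinery, alters miRNA levels in cells depleted of these Hippo pathway components. Between 81254 and 124970 counts over miRNA probes were recovered per sample, and 168 miRNAs lay above the detection minimum. Log2 signals of these correlated across miRNAs at 0.981 between the control samples and 0.993 between the p72 samples, against 0.903 to 0.918 across groups. Those correlations are over miRNAs within samples, and miRNAs are not independent replicates.

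A set of 9 miRNAs was higher in p72 past the threshold under every one of 10 scalings of the samples, and 4 were lower under every one. On the deposited scale the largest difference was that of miR-210, a miRNA induced by low oxygen. It rose 9.62-fold, from 29.8 ± 5.13 to 295 ± 39.9 (mean signal ± SD, n = 2 per group). Its log2 difference was 3.27 (SE 0.24, limma adjusted p = 1.09e-32). miR-301a-3p rose 6.17-fold (108.5 to 675.6), and the neighbouring miRNAs miR-30b-5p and miR-30d-5p of the miR-30 family rose 5.01-fold and 3.74-fold. miR-425-5p (4.13-fold), miR-4516 (4.21-fold), miR-575 (3.82-fold), miR-4286 (3.82-fold) and miR-582-5p (3.76-fold) completed this set. The 4 lower miRNAs were miR-3676-3p (6.23-fold lower, from 222 ± 46.5 to 34.4 ± 2.06), miR-1246 (2.71-fold lower, from 1792 ± 136 to 660 ± 45.0), miR-4455 (1.97-fold lower) and miR-1286 (1.71-fold lower). The call of miR-1286 was lost in 3 of the 4 fits with a sample left out: without control replicate 1 (adjusted p = 0.0694 in limma), control replicate 2 (adjusted p = 0.0584) or p72 replicate 2 (adjusted p = 0.174). Over the 10 scalings the log2 difference ranged from 2.36 to 3.27 for miR-210 and from 1.58 to 2.63 for miR-301a-3p. It ranged from -3.64 to -2.64 for miR-3676-3p and from -2.61 to -1.44 for miR-1246. For miR-4455 it ranged from -1.96 to -0.98 and for miR-1286 from -1.68 to -0.77. The deposited scale gave the upper end of each of these ranges. Where miR-210 was at its lowest, miR-3676-3p had the larger difference. The control means of miR-210, miR-4516, miR-575, miR-4286 and miR-30d-5p and the p72 means of miR-3676-3p, miR-4455 and miR-1286 lay below the detection minimum of 52.6, so those folds were measured against background.

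**Figure D1:**
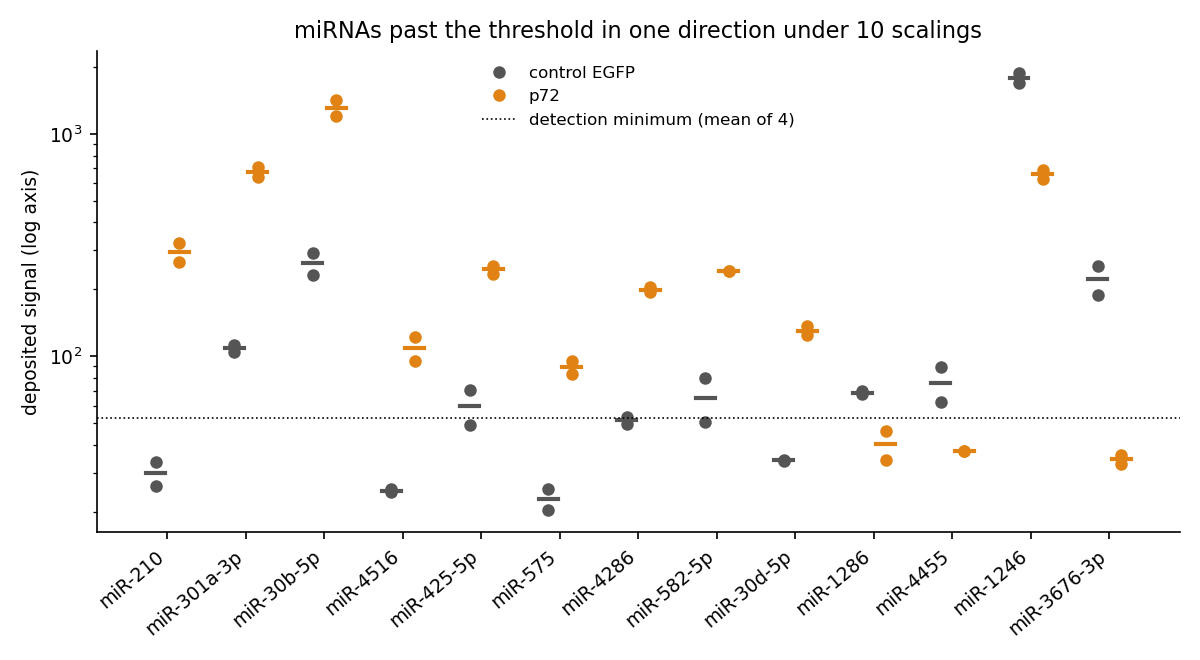
Deposited signal (log axis) of the 13 miRNAs past the threshold in one direction under all 10 scalings, in EGFP control samples (grey) and p72 samples (orange). Each point is 1 sample, each short bar the group mean (n = 2), and the dotted line the detection minimum of 52.6, which applies to the mean of the 4 samples; in each miRNA the groups do not overlap.

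On the deposited scale, 117 of the 168 detected miRNAs passed the threshold, 110 of them higher and 7 lower in p72. The miRNAs with the largest rise after miR-210 and miR-301a-3p were miR-29b-3p (5.48-fold, 310 ± 115 to 1641 ± 22.3) and miR-32-5p (5.45-fold, 265 ± 141 to 1343 ± 79.1), followed by miR-30b-5p and miR-324-5p (4.82-fold, 151 ± 29.7 to 725 ± 8.33). The adjusted p of these was 1.44e-22 for miR-29b-3p, 1.44e-22 for miR-32-5p and 7.74e-20 for miR-324-5p (limma). With quantile normalization these did not pass (adjusted p = 0.0678, 0.108 and 0.0503 in limma), nor did miR-32-5p with DESeq2 (adjusted p = 0.0781). Of the 110 that rose, 65 rose by more than 2-fold. The other 3 miRNAs that fell on this scale, miR-302d-3p (1.50-fold lower, adjusted p = 0.0164), miR-1324 (1.47-fold lower, adjusted p = 0.0324) and miR-378e (1.43-fold lower, adjusted p = 0.0324), changed less and passed under 7, 8 and 7 of the 10 scalings. The call of miR-302d-3p was lost without p72 replicate 1 or 2 (adjusted p = 0.267 and 0.265 in limma). That of miR-1324 was lost whichever of the 4 samples was left out (adjusted p from 0.0569 to 0.28). That of miR-378e was lost without control replicate 2 (adjusted p = 0.0573), p72 replicate 1 (0.253) or p72 replicate 2 (0.394). The next in that direction had lower values in both p72 samples without passing the threshold in limma: miR-7-5p (log2 difference -0.45, adjusted p = 0.0853), miR-504 (-0.42, adjusted p = 0.104), miR-1283 (-0.35, adjusted p = 0.144), miR-489 (-0.30, adjusted p = 0.234) and miR-520h (-0.27, adjusted p = 0.299). Each of these 5 was lower past the threshold under 6 of the 10 scalings. In all 117 the values of the groups did not overlap. Such separation was seen in 86.3% of the detected miRNAs, where chance gives 33.3%, but miRNAs of a sample share its factor and are not independent in this count.

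**Figure D2:**
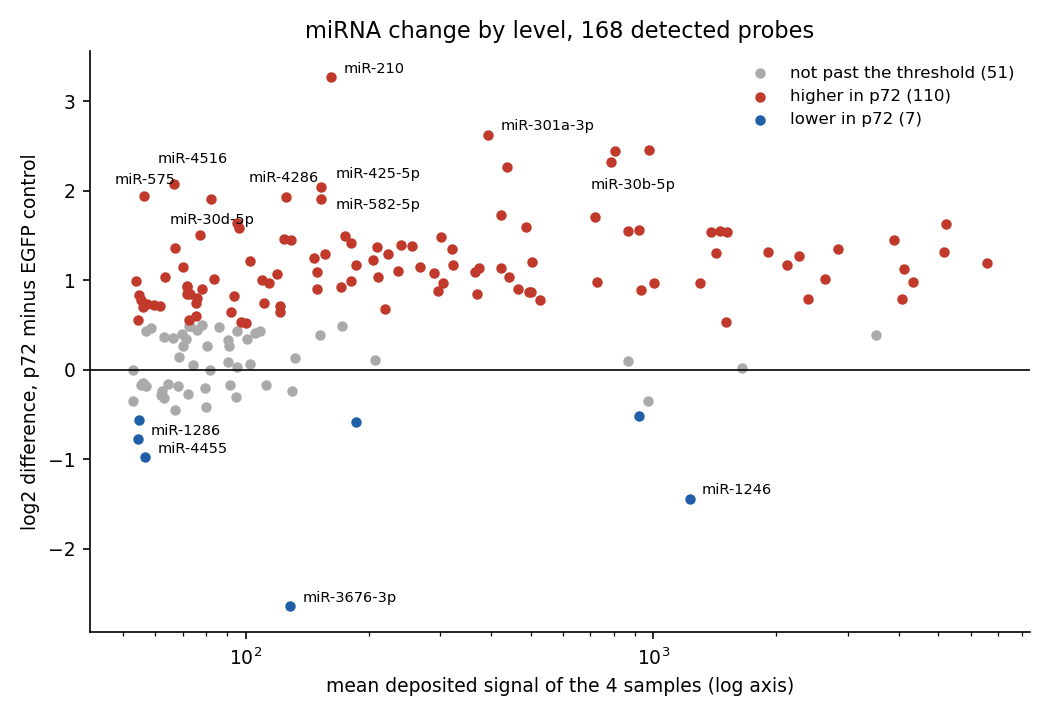
Log2 difference between p72 and EGFP control samples (n = 2 each) against the mean deposited signal of the 4 samples (log axis), one point for each of the 168 detected miRNAs. Red marks the 110 higher and blue the 7 lower miRNAs past the threshold on the deposited scale, grey the 51 not past it, and names are given for the 13 that passed in the same direction under all 10 scalings.

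The bulk of the detected miRNAs stood higher in p72 on the deposited scale, and this shift depended on the scaling. The deposited factors brought all 800 miRNA probes, 632 of them undetected, to nearly the same geometric mean. On that scale a fall of the undetected probes appears as a rise of the detected ones. Over the detected miRNAs the median log2 difference was 0.86 (1.81-fold, interquartile range 0.35 to 1.25). By sign alone, without regard to the threshold, 141 of the 168 miRNAs were higher and 27 lower. Over all 800 probes, without the filter, the median was -0.11, with 350 higher and 450 lower. The 5 miRNA probes of highest mean over the 4 samples belonged to the proliferation-linked miR-17/92 group and to the miR-15/16 family, although in the controls alone miR-4454 ranked second (3048): the probe shared by miR-106a-5p and miR-17-5p rose from 4045 ± 883 to 9120 ± 435, miR-15b-5p from 2591 ± 691 to 7859 ± 375, miR-19b-3p from 2971 ± 577 to 7328 ± 366, the probe of miR-20a-5p and miR-20b-5p from 2938 ± 573 to 5743 ± 524, and miR-25-3p from 2599 ± 590 to 5614 ± 435. The call of the miR-20a-5p and miR-20b-5p probe was lost without p72 replicate 1 (adjusted p = 0.0535 in limma). The sample medians (log2) were 6.44 and 6.67 in the controls and 7.22 and 7.27 in p72, with an exact two-sided permutation p of 0.333, the smallest that 2 against 2 samples can give. The miRNA total, the median of the detected miRNAs, quantile normalization, TMM and DESeq2's size factors align samples on the miRNAs themselves. They remove most of a general rise by construction, so their small medians do not test for one. The positive controls, the mRNA references and counts without scaling do not use the miRNA probes. None of these scales was shown here to follow the amount of RNA. The mRNA references did not change alike, from -0.67 (ACTB) to 1.24 (GAPDH) in log2 difference on the deposited scale. With the miRNA total set equal the median difference was 0.02, and by sign 87 miRNAs were higher and 81 lower. With the positive controls set equal it was -0.04 with 80 higher and 88 lower by sign, with edgeR's TMM -0.09 with 72 and 96, and with DESeq2's size factors 0.01 with 85 and 83. The mRNA references gave 0.52 with 129 and 39, the median of the detected miRNAs 0.17 with 101 and 67, and quantile normalization 0.05 with 91 and 75. Counts without scaling gave 0.21 with 104 and 64, and RPL19 with RPLP0 0.29 with 105 and 63. The miRNAs past the threshold, 110 higher and 7 lower on the deposited scale, became 40 higher and 44 lower with the total, 25 and 37 with the positive controls, 33 and 59 with TMM, and 27 and 35 with DESeq2. They were 38 and 4 with the mRNA references, 55 and 37 with the median, 25 and 23 with quantile normalization, 12 and 5 with counts without scaling, and 12 and 4 with RPL19 and RPLP0. Of the 110 miRNAs called higher on the deposited scale, 2 were called lower under another scaling, miR-129-2-3p with TMM and miR-196b-5p with TMM and with quantile normalization. Without p72 replicate 1 or 2, neither was called (adjusted p = 0.281 and 0.276 for miR-129-2-3p, 0.259 and 0.325 for miR-196b-5p, in limma). Nor was miR-196b-5p called without control replicate 1 (adjusted p = 0.06).

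**Figure D3:**
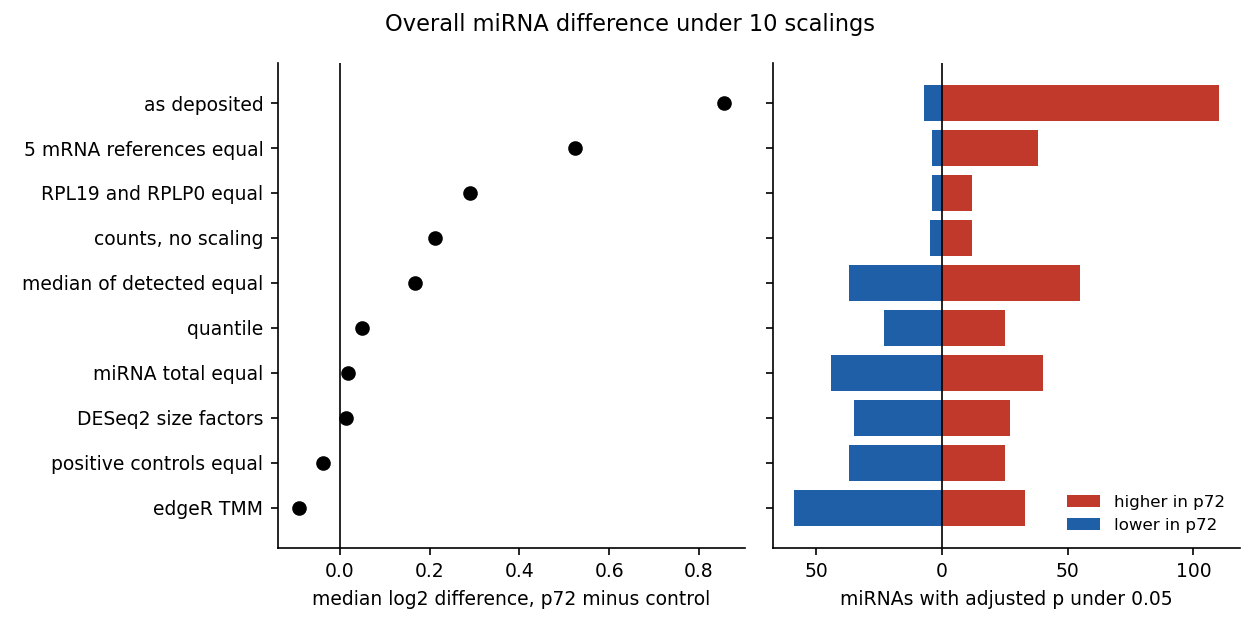
Left, median log2 difference (p72 minus EGFP control) over the 168 detected miRNAs under 10 scalings, running from 0.86 as deposited to -0.09 with edgeR's TMM factors. Right, number of miRNAs with an adjusted p under 0.05 under the same scaling, higher in p72 in red to the right of 0 and lower in blue to the left; n = 2 per group.

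Among the families, whose members past the threshold are counted on the deposited scale, the miR-30 family had the highest median: all 5 detected members rose, among them miR-30a-5p (2.83-fold) and miR-30e-5p (2.33-fold), with a median log2 difference of 1.50 that stayed between 0.56 and 1.50 over the 10 scalings. In the miR-17/92 cluster and its paralogs 9 of 9 detected members rose (median 1.27, 0.08 to 1.27 over the scalings). The miR-29 family, with 2 of 3 past the threshold including miR-29c-3p (2.45-fold), had a median of 1.29 and stayed above 0 under every scaling. So did the miR-15/16 family (4 of 4 detected, median 1.23, miR-15a-5p 2.55-fold), the family of miR-130 and miR-301 with miR-454 (4 of 4, median 1.22, miR-454-3p 2.56-fold, miR-130b-3p 2.14-fold), the miR-181 family (2 of 2, median 1.28, miR-181a-5p 2.67-fold, the probe of miR-181b-5p and miR-181d 2.22-fold) and the miR-23/27/24 clusters (4 of 4, median 1.10, miR-23a-3p 2.63-fold, miR-27b-3p 2.20-fold). In the let-7 family, linked to differentiation, 6 of 9 rose, with 2.02-fold for let-7a-5p, 2.13-fold for let-7e-5p and 1.79-fold for let-7b-5p, but its median of 0.73 fell to 0 or below under 5 of the 10 scalings. The miR-99/100 and miR-125 group had 4 of 5 past the threshold, with miR-125a-5p at 2.94-fold, miR-99a-5p at 2.25-fold and miR-125b-5p at 1.96-fold; its median of 0.97 went below 0 under 1 scaling. The call of miR-125b-5p was lost without p72 replicate 2 (adjusted p = 0.0811 in limma). Under the other 9 scalings the members that passed upwards numbered 2 to 4 in the miR-30 family, 0 to 7 in the miR-17/92 group and 1 to 3 in the miR-130 and miR-301 family. They numbered 0 to 2 each in the miR-29 family, the miR-15/16 family, the miR-23/27/24 clusters and the miR-99/100 and miR-125 group, and 0 to 1 each in the miR-181 and let-7 families.

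Of 7 measured miRNAs whose processing earlier work tied to p72, its relative p68 or their partners, 3 were detected, and miR-15a-5p, miR-16-5p (1.72-fold) and miR-21-5p (1.72-fold) rose on the deposited scale. miR-16-5p and miR-21-5p passed under none of the other 9 scalings. The call of miR-16-5p was also lost without p72 replicate 1 or 2 (adjusted p = 0.136 and 0.0792 in limma). That of miR-21-5p was lost without control replicate 1 (adjusted p = 0.175) or p72 replicate 1 (0.348). Their median of 0.79 was below that of the other miRNAs (0.86) although camera placed the list above them by its mean, and it went to 0 or below under 5 of the 10 scalings. Of 16 miRNAs reported to be made without Drosha, the nuclease of the Microprocessor, 3 were detected: miR-484 (1.68-fold) and miR-1234 (1.89-fold) rose on the deposited scale and under none of the other 9, and miR-1226-3p was at 53.1 ± 13.0 and 52.7 ± 9.32 (adjusted p = 0.998 in limma). The call of miR-484 was lost without control replicate 1 (adjusted p = 0.163 in limma), control replicate 2 (0.0741) or p72 replicate 1 (0.299). The median of this list was 0.75 and went to 0 or below under 4 scalings.

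None of the 12 lists tested differed from the other miRNAs past the threshold. The lowest adjusted p by camera was 0.228, for the miR-30 family (p = 0.0310) and the keratinocyte list (p = 0.0381), and the lowest with an estimated correlation was 0.816; 2 lists had an unadjusted camera p under 0.05. By fry, which asks whether a list's members move one way without comparing them with other miRNAs, 9 of the 12 passed, all upwards. Adjusted over the list alone, each list had as many members past the threshold as over all detected miRNAs.

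Several miRNAs abundant in cultured keratinocytes were at background in all 4 samples. Of the 14 measured miRNAs of the keratinocyte list, 7 were detected and all 7 rose on the deposited scale, including miR-210, miR-221-3p (2.91-fold), miR-125b-5p, miR-21-5p and miR-27b-3p. Under the other 9 scalings 1 to 4 of them passed upwards, and the list median lay between 0.08 and 1.14 over the 10. The undetected ones included miR-205-5p, at 21.5 ± 2.89 in the controls and 24.5 ± 5.70 in p72, miR-203, at 19.3 ± 3.39 and 27.5 ± 9.40, and miR-31-5p, at 29.9 ± 10.1 and 43.2 ± 10.4. None of the 5 members of the epithelial miR-200 family was detected; miR-200c-3p was at 29.3 ± 3.27 and 48.1 ± 0.346, and miR-141-3p at 44.8 ± 5.86 and 52.9 ± 12.1. miR-145-5p (27.9 ± 0.113 and 25.1 ± 6.47), miR-199a-5p (26.7 ± 1.90 and 32.03 ± 9.06), miR-320a (46.9 ± 7.81 and 24.8 ± 3.71) and miR-877-5p (16.5 ± 2.91 and 14.5 ± 1.21) were not detected either, and miR-143-3p was at 1 count in every sample.

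Markers of other cell types were mostly undetected, and those detected moved in both directions on the deposited scale. Of 10 neural miRNAs 3 were detected and 2 rose: miR-9-5p at 3.03-fold (241 ± 29.7 to 731 ± 106), and miR-129-2-3p at 1.44-fold, which was lower with TMM. miR-126-3p, an endothelial miRNA, rose 3.31-fold and was the 1 detected of 4 liver, endocrine, melanocyte and endothelial miRNAs. Among 9 miRNAs of pluripotent cells 2 were detected, 1 higher and 1 lower (miR-302d-3p). None of 8 muscle miRNAs was detected, and of 7 blood cell miRNAs 2 were detected and 0 passed the threshold. Of the 40 miRNAs listed for the placental chromosome 19 cluster miR-520h was the 1 detected, and it did not pass. That list did not hold miR-1283, which was detected (means of 1088 in control and 856 in p72), so it does not speak for the whole cluster. In the imprinted DLK1-DIO3 cluster 2 of 47 were detected and 1 rose (miR-494, 1.87-fold). Of 7 p53-linked miRNAs 2 were detected: miR-194-5p rose 2.44-fold, and miR-192-5p was at 119 ± 6.96 and 106 ± 5.08 (adjusted p = 0.514 in limma). Medians of the neural list (0.52), the blood list (0.27), the pluripotent list (0.11), the p53-linked list (0.56) and the DLK1-DIO3 list (0.48) went to 0 or below under between 7 and 9 of the 10 scalings. Under the other 9 scalings 0 to 1 members of the neural and p53-linked lists passed upwards and 0 of the pluripotent and DLK1-DIO3 lists. Camera placed the neural list above the rest by its mean although its median was lower.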

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

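The tests in this part were chosen after the results were seen, except the scalings by the positive controls, the miRNA total and the mRNA references, which were planned. Among the 10 mRNA, plant and worm probes outside the miRNA comparison, 3 stood higher in both p72 samples than in both controls on the scale of the miRNA probes. GAPDH, a glycolytic enzyme that served as an mRNA reference, was higher by 1.24 on the log2 scale, and RPLP0, a ribosomal protein mRNA, by 0.77. The probe for the rice miRNA osa-miR442 was higher by 1.65. Within samples, the ratio of GAPDH to RPL19 counts was 0.764 and 0.685 in the controls and 1.34 and 1.30 in p72, and that of ACTB to RPL19 was 0.243 and 0.242 against 0.119 and 0.116. GAPDH and osa-miR442 stayed higher under the 7 scalings applied to them, from 0.34 and 0.77 with the positive controls set equal, whereas RPLP0 went to -0.13. ACTB (-0.67) and the worm probe cel-miR-248 (-0.70) were lower in both p72 samples, and the groups overlapped in the other 5 probes. The counts of osa-miR442 were 47 and 37 in the controls and 107 and 68 in p72, and its source was not tested.

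The pattern most open to processing is that most detected miRNAs were higher in p72 on the deposited scale. A lower assay background in the p72 samples is argued against only in the form shared by the negative controls. On the common scale these changed by 0.30 on average and the 632 undetected miRNA probes by a median of -0.20. The difference of 0.50 exceeds the SD over negative controls (0.22). Median counts of the undetected probes were 25 and 24 in the controls and 17 and 11 in p72. A fall in the background of the miRNA probes alone is not covered by this test and stays open. The authors' scaling remains a candidate explanation. The median difference was -0.037 with the positive controls set equal, but 0.52 with the mRNA references, among which GAPDH and ACTB moved in opposite directions. The spread of the sample medians was 0.12 on the deposited scale, which only the second value exceeds. That spread was not computed anew for the other scalings. The miRNA total gave 0.02, which cannot decide this because it removes most of a general rise by construction. Loss of miRNAs of low GC content in the control extractions also stays open. The 4 detected miRNAs reported to be lost in TRIzol extraction all rose on the deposited scale. Their median was 1.45, at the 90.5th percentile of 10000 lists matched on level. Camera placed them above the rest (unadjusted p = 0.0469, and p = 0.179 with an estimated correlation). A change in processing caused by p72 is a further open explanation that the design confounds with these.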

How the results depend on the processing

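The 9 higher and 4 lower miRNAs that passed under all 10 scalings also passed in the same direction under every other setting in which they were tested, except miR-1286, which lost its call without either control sample and without p72 replicate 2. With a sample left out, its group keeps 1 sample, assumed to vary like the other group, whose pair gives all of the spread. The cause of the changes below was not tested, except where the scaling factor itself moves every miRNA. The count of 117 became 42 with the mRNA references, 62 with the positive controls, 62 with DESeq2, 48 with quantile normalization, 17 with unscaled counts, 16 with RPL19 and RPLP0, 178 (127 higher, 51 lower) without a filter and 57 (55 and 2; 61 tested) with a filter 4 times higher. It was 92 with the median, 84 with the total, 92 with TMM, and between 78 and 126 with a sample left out. The median log2 difference of 0.86 became 0.523 (mRNA references), 0.29 (RPL19 and RPLP0), 0.212 (unscaled counts), 0.168 (median), 0.0486 (quantile), 0.0170 (total), 0.0125 (DESeq2), -0.0368 (positive controls), -0.0912 (TMM), -0.111 (no filter, which adds probes at background), 1.136 (higher filter), 0.666 (pseudocount 32) and 0.988 (background subtracted), and lay between 0.683 and 1.017 with a sample left out. The number of lists past the threshold stayed at 0 under 20 of 23 settings and became 1 with quantile normalization (the miR-30 family) and 9 with fry. Without a filter all 21 lists were tested and 12 passed, among them the placental and DLK1-DIO3 lists downwards (camera adjusted p = 0.021 and 0.0349). There the lists were compared mostly with the 632 undetected probes, so a pass can reflect how many members were detected.

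Of 1361 values of 58 named miRNAs under the alternatives, 41 reversed. With the total they were miR-21-5p -0.0632, miR-16-5p -0.0596 and miR-484 -0.0874; with the positive controls -0.117, -0.114 and -0.141 for the same miRNAs and -0.0462 for let-7b-5p; with DESeq2 -0.0363, -0.0730 and -0.0404 for miR-21-5p, miR-16-5p and miR-484. With TMM they were miR-21-5p -0.143, miR-16-5p -0.182, miR-484 -0.121, miR-1234 -0.0211, miR-494 -0.0446 and let-7b-5p -0.0947. With quantile normalization they were miR-20a/20b -0.0852, let-7e-5p -0.121, miR-125b-5p -0.165, miR-21-5p -0.313, miR-27b-3p -0.113 and miR-16-5p -0.217. miR-129-2-3p and miR-196b-5p were -0.164 and -0.158 with the median, -0.315 and -0.310 with the total, -0.369 and -0.365 with the positive controls, -0.121 and -0.114 with unscaled counts, -0.0428 and -0.0354 with RPL19 and RPLP0, -0.0647 and -0.367 with quantile normalization, -0.428 and -0.424 with TMM, and -0.325 and -0.319 with DESeq2. miR-1226-3p, close to 0 on the deposited scale, lay between -0.249 and 0.248 with a sample left out and was 0.0204 by edgeR with the deposited factors.

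Same-numbered samples deviated from their group means in opposite directions (correlation over miRNAs -0.174), and the replicate number as a block gave 119 miRNAs (112 higher, 7 lower). With crossed numbers as a block 110 were called (104 higher, 6 lower). Plant and worm probes averaged 26.4 to 38.0 counts per sample, against 14.8 to 28.3 for the negative controls, and were not used as a scale. Signal over background limits the comparison to 168 of 800 miRNAs.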

Other observations

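The tests in this part were chosen after the results were seen, and so were their lists except that of Drosha-independent miRNAs. Neighbouring miRNA genes changed alike on the whole. Over 29 pairs of detected miRNAs whose genes lie within 10 kb of each other, the changes differed by a mean of 0.577 on the log2 scale, against a median of 0.842 in 10000 permutations (permutation p = 0.0204). A pair that moved together was miR-221-3p and miR-222-3p (1.54 and 1.35, a difference of 0.19, and of 0.12 after subtraction of background). In 13 of the 29 pairs, some of which share a member, the miRNAs nevertheless differed past the threshold (limma on the difference within samples, which no scaling by 1 factor per sample can alter beyond the pseudocount). miR-425-5p exceeded its neighbour miR-191-5p by 1.08 (adjusted p = 0.000103). On the X chromosome miR-362-5p exceeded miR-532-5p by 1.25 (adjusted p = 1.66e-05), and miR-503 exceeded miR-450b-5p by 1.30 (adjusted p = 1.66e-05). These differences were 1.58, 1.84 and 1.70 after subtraction of background. The control mean of miR-362-5p (47.7) lay below the detection minimum of 52.6. Most of the 13 pairs lay on the X chromosome, among miR-188, miR-362, miR-532 and miR-660 or among miR-450b, miR-503 and miR-542, so they are not 13 separate places in the genome. A change shared by the members of a cluster may account for the likeness. The permutations were not matched on level, so they do not separate such a change from a likeness in level. Steps after transcription could account for the differences, which were not tested further.

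A group of probes stood outside the general rise. Of 6 detected probes named as miRNAs but placed by earlier work in genes of tRNAs, U2 snRNA or snoRNAs, 0 rose and 2 fell (miR-1246 and miR-3676-3p) on the deposited scale. The other 4 did not pass there: miR-720 (1641 and 1659), miR-1260a (839 and 897), miR-4454 (3048 and 3982) and miR-1290 (59.8 and 46.2, means of control and p72). Values of miR-4454 and miR-1260a were higher in both p72 samples on that scale. Over the 10 scalings, miR-720 and miR-1260a passed downwards under 6 and miR-4454 and miR-1290 under 5, and upwards under 0. The median log2 difference of all 6 probes, -0.17, lay at the 0.33rd percentile of 10000 lists matched on level. The list was drawn up after its largest changes had been seen, so this decides nothing about the level of these probes on the panel as the reason. One hypothesis is that RNAs made without Drosha do not rise with p72. The median of the 3 detected Drosha-independent miRNAs lay at the 73.8th percentile of lists matched on level, and miR-484 and miR-1234 among them rose on the deposited scale and under none of the other 9. With 3 members near background this leaves the hypothesis open without support, and other sources of such fragments stay open.

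The miRNAs abundant in cultured keratinocytes that lay at background raise the question of what the assay saw. Of 8 miRNAs abundant in cultured keratinocytes (miR-205-5p, miR-203, miR-31-5p and the miR-200 family) 0 passed the detection minimum, with single values between 11.7 and 61.5. In control replicate 1, miR-141-3p of this family, at 58 counts, exceeded that sample's mean plus 2 SD of the negative controls (47.6 counts). The second most dilute positive control was at least 1.68 times the mean plus 2 SD of the negative controls in each sample. The most dilute one was 0.505 and 0.745 times that limit in the controls and 1.03 times in both p72 samples. An assay too insensitive for low levels thus stays open only for levels below that of the second most dilute control. It would not account for the absence of miRNAs that were abundant in these cells. For levels below that control, low sensitivity, probes that fail for these miRNAs alone, and cells other than the labelled keratinocytes cannot be told apart here. For higher levels, failing probes and other cells cannot be told apart. No marker list of another line had been fixed, and no reference sample of the line was used here. The lists of other cell types written beforehand were detected in part or not at all. Detected were 3 of 10 neural, 2 of 7 blood cell, 0 of 8 muscle and 2 of 9 pluripotent miRNAs. In the list of liver, endocrine, melanocyte and endothelial miRNAs it was 1 of 4. Among the miRNAs that were abundant, miR-196b-5p had mean signals of 1234 and 1777 and miR-10a-5p of 831 and 2019 in control and p72.

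The rises of miR-210 and of the GAPDH mRNA, both known to increase in low oxygen, suggest the hypothesis of such a response in the p72 cultures. The other 8 detected miRNAs reported to rise in low oxygen all rose on the deposited scale (median 1.14, against 0.84 for the rest), where 110 of 168 rose. Among 10000 lists matched on level the median was 1.05, and 1.14 lay at the 70.0th percentile. Camera did not separate this list from the other miRNAs (p = 0.168; p = 0.486 with an estimated correlation), which leaves the question open.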
